A study of Mus musculus with 10 samples.

How the data were processed

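RNA was measured in 10 flank tumours of the human DAOY line from nude mice, all at day 30. The sample titles (CTRL, OIL and FO) and the treatment label together gave 3 groups: control chow (n = 3), DHA oil (n = 3) and fish oil (n = 4). Per the labels' protocols, libraries were made with a stranded poly(A) mRNA kit and read as single 75 bp ends. The deposited table holds raw counts, whole numbers of reads per gene for 33538 human Ensembl gene identifiers, and the authors did not normalise them as far as the values show. Reads were aligned with STAR to GRCh38 and counted with HTSeq 0.9.0, per the submitters' processing notes. The annotation release, the strand setting of the counting, the handling of reads shared by several genes and any removal of mouse reads are not given in the sources used here. Counts of overlapping, antisense or near-identical genes are therefore uncertain, and mouse reads similar enough to human genes to align could be among the counts. GEO lists the organism as mouse, the host of the grafts, while the counts are of human genes.

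The reference tables at hand cover mouse genes and matched 0 of the 33538 identifiers, and the count table does not pair identifiers with names. No gene is named, and no position is given, for that reason. The 36 gene lists fixed before the data were examined hold 811 human symbols, of which 0 could be matched, so no list was tested and markers of host cell types could not be measured. Genes described singly follow a rule also fixed before the data were examined. It takes genes past the threshold, with a mean log2 CPM of at least 1 and no overlap between the 2 groups. Where fewer than 5 genes are called, it adds those with the smallest p in each direction under the same other conditions. A statement that the groups of such a gene do not overlap therefore restates its selection. Of all genes tested, 10.6% did not overlap between DHA oil and control (10% by chance), 3.74% between fish oil and control and 4.95% between the oils (5.71% by chance for both). For both oils together against control the share was 1.12% (1.67% by chance). Because identifiers could not be matched to names, it was capped at 2 identifiers per direction. The lower pair are the first 2 by p in DHA oil against control. Each higher one is the first by p among higher genes that met the conditions, in fish oil against control and in fish oil against DHA oil. Parts of the rule that listed genes by symbol could not be applied.

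Genes with low counts were removed with filterByExpr (minimum count 10), which left 16013 genes. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, in 1 fit of all 10 libraries with diet as the only factor and Benjamini-Hochberg adjustment over the genes tested in each comparison, with a threshold of 0.05. The comparisons were each oil against control, fish oil against DHA oil, and the mean of both oils against control. The SE of a log2 fold change was derived from the test, as its absolute value divided by the square root of the F statistic. It is therefore not a direct measure of the spread between libraries. Intervals of log2 fold changes are 95%, are built on this SE and use the total degrees of freedom of the test (median 14.7). These are the residual ones plus those gained by sharing information on spread across genes. Log2 CPM values use a prior count of 2. Total counts ranged from 6187116 to 10035702, and the common biological coefficient of variation was 0.163. In simulated counts with these library sizes and 100 genes changed at each of 2 sizes, the test recovered 67% of 2-fold and 93% of 4-fold changes for DHA oil against control, 73% and 95% for fish oil against control, 72% and 97% for fish oil against DHA oil, and 73% and 98% for both oils against control. False calls numbered 10 of 170, 10 of 178, 8 of 177 and 14 of 185. The adjusted threshold is stricter when fewer genes change, so these shares do not hold for comparisons with few changed genes.

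Similarity of the oils was set beside 30 simulations with no effect of diet. In each, all 10 libraries, controls included, were drawn around 1 common mean per gene, and both oils shared the simulated controls. Cell cycle sets were added after the identifiers had been seen. They are the 100 genes per phase that lead the human marker pairs distributed by Ensembl identifier with scran 1.30.0, and were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Alternatives fixed before the data were examined were other scaling factors, no filter and a strict filter on low counts, DESeq2 1.42.0, limma-voom with quality weights, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. A score of the called genes as a covariate, and the removal of 2 libraries together, were added later. No batch is given in the labels.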

Results

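Tumours of DAOY, an established human medulloblastoma cell line, were grown under the skin of the flank in nude mice, an immunodeficient strain that accepts human grafts. The mice ate ordinary chow (control) or received an oil, and tumours were profiled by bulk mRNA sequencing after 30 days of treatment. One oil supplied docosahexaenoic acid (DHA). The other, labelled fish oil, was taken to be the arm that combined DHA with eicosapentaenoic acid (EPA). Both are long-chain omega-3 polyunsaturated fatty acids. There were 3 control, 3 DHA oil and 4 fish oil libraries, each a separate sample of its group. Nothing in the labels ties a library to a mouse, so p-values measure the spread between these samples. Total counts per library ranged from 6187116 to 10035702. They lay between 7412470 and 9390741 in control, between 8428137 and 10035702 in DHA oil, and between 6187116 and 9588388 in fish oil. The values are the deposited raw counts of reads per human gene, given here as CPM, counts scaled to the effective library total. Libraries of one group correlated at r = 0.961 to 0.986 across genes (median 0.980). Those of different groups were as alike, at 0.963 to 0.987 (median 0.979), and no pair agreed within sampling noise. The count table pairs no gene name with its Ensembl identifiers, so genes are given by identifier and 4 are described singly.

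The first question was what omega-3 supplementation as a whole changed, taking both oils together against ordinary chow. In the oil-fed tumours 21 of 16013 genes tested were lower than in control and 0 were higher. Among them, ENSG00000101470 stood at 26.3 ± 29.7 CPM in control (SD, n = 3), 1.53 ± 0.51 CPM in DHA oil (SD, n = 3) and 0.794 ± 0.134 CPM in fish oil (SD, n = 4). It was 23.7-fold lower with the oils, a log2 fold change of -4.57 ± 0.53 (SE), and control replicate 1 set much of that size, since the log2 fold change was -3.06 without it. ENSG00000109846 fell from 22.6 ± 2.84 CPM in control (SD, n = 3) to 8.15 ± 2.87 CPM in DHA oil (SD, n = 3) and 8.20 ± 2.18 CPM in fish oil (SD, n = 4), which was 2.78-fold lower, a log2 fold change of -1.47 ± 0.20 (SE). All 7 oil libraries lay below all 3 controls for both genes, which their selection required of the DHA oil libraries.

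The fall of the 21 genes was deep, with log2 fold changes from -6.05 to -1.47 and a median of -3.71. Without control replicate 1 the median was -2.31. Each of the 21 was lower at an unadjusted p under 0.05 in DHA oil and in fish oil taken singly, with a median log2 fold change of -3.12 and -4.20, which follows in part from their selection on the mean of both oils against the same controls. Their mean log2 CPM was 3.96 ± 1.30 in control (SD, n = 3), 1.24 ± 0.82 in DHA oil (SD, n = 3) and 0.63 ± 0.48 in fish oil (SD, n = 4). The controls did not carry these transcripts evenly. Control replicate 1 held the highest value of 18 of the 21 genes. Over all 21 it stood at a median of 5.43 times the mean of the other controls. Its mean log2 CPM over the genes was 5.43 against 2.94 and 3.53 in control replicates 2 and 3. The highest of the 7 oil libraries, DHA oil replicate 1, reached 1.98. Within the 7 oil libraries alone, deviations of the 21 genes from their diet means had a mean pairwise correlation of 0.393, against at most 0.166 in 1000 random sets of genes matched on expression, and 2 of the 21 had a negative mean correlation with the rest.

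**Figure D1:**
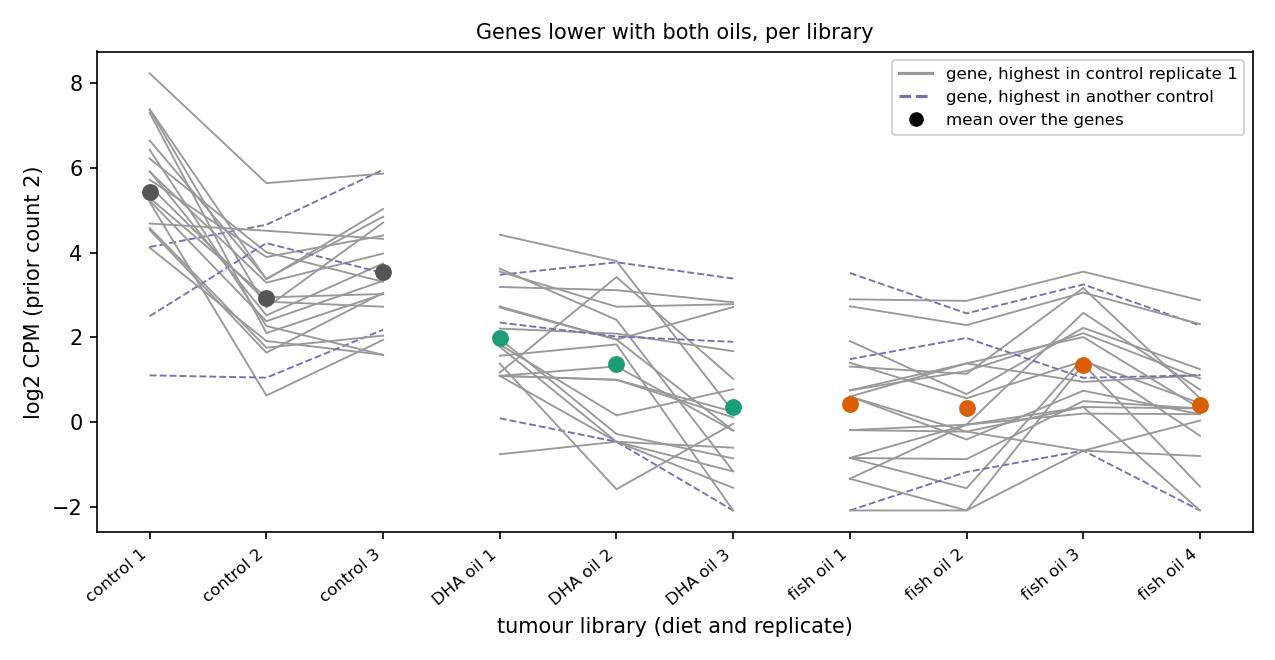
Log2 CPM (vertical axis, prior count 2) of the 21 genes lower with both oils in each of the 10 tumour libraries (horizontal axis), with 1 line per gene within each diet and a dot for the mean over the genes. The 3 control means lie between 2.94 and 5.43, above the 7 oil means, which lie between 0.34 and 1.98.

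These genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.00702 for ENSG00000101470 and 0.0123 for ENSG00000109846). At an unadjusted p under 0.05 there were 419 genes, below the 801 that chance gives with no effect. DESeq2 called 29 lower and 1 higher (ENSG00000164035), and limma-voom called 1 (ENSG00000109846). With no filter on low counts edgeR called 76, of which 75 were lower and 1 was higher, again ENSG00000164035. The edgeR count was 3 without control replicate 1, where ENSG00000109846 was no longer called (log2 fold change -1.38), 4 without fish oil replicate 2, 5 without fish oil replicate 4, 6 without DHA oil replicate 2, 8 without DHA oil replicate 3, 12 without fish oil replicate 1 and 35 without control replicate 2, in each case lower genes only. With both control replicate 1 and fish oil replicate 4 left out, 3 genes were called.

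The second question was the effect of DHA oil against ordinary chow. No gene passed the threshold after the filter on low counts, and 57 did with no filter (53 lower and 4 higher). The lowest p-values belonged to the same pair of genes, ENSG00000101470 with a log2 fold change of -4.11 (95% interval -5.58 to -2.63; -2.60 without control replicate 1) and ENSG00000109846 with -1.48 (-2.02 to -0.94), each lower in 3 of 3 DHA oil libraries than in every control. Both had an adjusted p of 0.186 in edgeR with the filter. In the other direction, ENSG00000164035 stood at 1.19 ± 0.245 CPM in control (SD, n = 3) and 3.62 ± 0.856 CPM in DHA oil (SD, n = 3), a log2 fold change of 1.60 (0.69 to 2.50) that was not called (adjusted p = 0.802). edgeR called 0 genes, with 438 at an unadjusted p under 0.05 (163 higher and 275 lower), whereas DESeq2 called 11 and limma-voom 3, all lower. Without DHA oil replicate 1 edgeR called 2 genes, and without control replicate 2 it called 5, with ENSG00000109846 called in the first case and ENSG00000101470 in the second.

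The third question was the effect of fish oil against ordinary chow. ENSG00000101470 was the 1 gene called, 32.6-fold lower with fish oil, a log2 fold change of -5.03 ± 0.69 (SE; adjusted p = 0.0456), and lower in 4 of 4 fish oil libraries than in every control. Without control replicate 1 the log2 fold change was -3.52 and the gene was still called. The value in control replicate 1 (60.3 CPM) was far above those in control replicates 2 (5.49 CPM) and 3 (13.1 CPM), and all of these exceeded the highest fish oil library (0.912 CPM). ENSG00000109846 had a log2 fold change of -1.47 (95% interval -1.97 to -0.97) and missed the threshold with an adjusted p of 0.0566. It was called by DESeq2, with no filter on low counts, in a fit of only these groups, and without DHA oil replicate 1 or control replicate 3. ENSG00000164035, the gene with the smallest p among those higher in fish oil that met the rule for genes described singly, stood at 4.08 ± 1.74 CPM (SD, n = 4) against 1.19 ± 0.245 CPM in control (SD, n = 3), a log2 fold change of 1.76 (0.89 to 2.62) that was not called (adjusted p = 0.392) but was called with no filter on low counts.

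**Figure D2:**
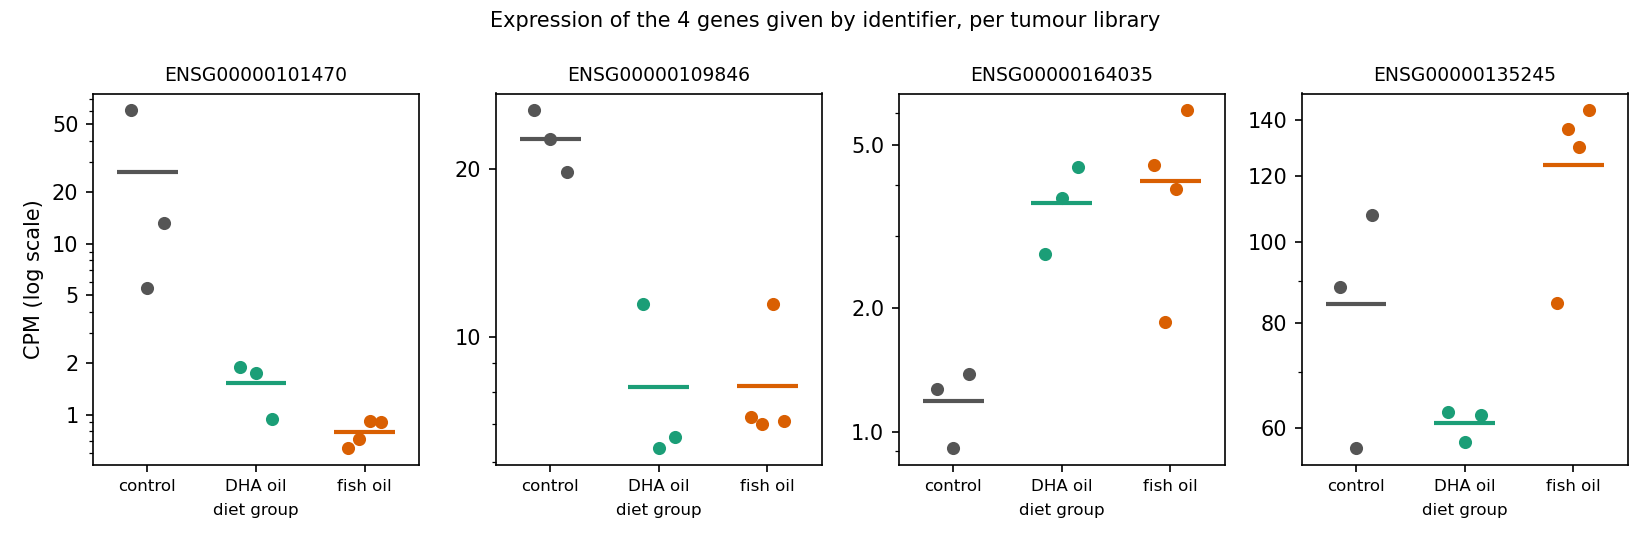
CPM on a log scale (vertical axis) of the 4 genes described singly, by diet group (horizontal axis), with a point per library and a bar at the group mean. The first pair is lower in all 7 oil libraries than in the 3 controls, ENSG00000164035 lies at 1.19 CPM in control on average and 4.08 CPM in fish oil, and ENSG00000135245 averages 60.9 CPM in DHA oil and 124 CPM in fish oil.

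At an unadjusted p under 0.05 there were 558 genes in this comparison, 263 higher and 295 lower. DESeq2 called 23 genes, all lower, limma-voom called 0, and edgeR with no filter on low counts called 56. The single call was lost when any one of the 4 fish oil libraries or DHA oil replicate 2 was left out, while its log2 fold change stayed between -5.10 and -4.96. The count rose to 3 without control replicate 1, 22 without control replicate 2, 19 without control replicate 3, 6 without DHA oil replicate 1 and 4 without DHA oil replicate 3, with ENSG00000101470 among them each time.

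The last question was whether fish oil, taken to be the arm that adds EPA to DHA, differed from DHA oil. edgeR called 0 genes, with 775 at an unadjusted p under 0.05 (432 higher and 343 lower) and a smallest adjusted p of 0.875. DESeq2 called 1 gene, ENSG00000135245, which also had the smallest p in edgeR. It stood at 124 ± 26.6 CPM in fish oil (SD, n = 4), 60.9 ± 2.78 CPM in DHA oil (SD, n = 3) and 84.3 ± 25.7 CPM in control (SD, n = 3). Its log2 fold change between the oils was 1.03 (95% interval 0.59 to 1.46), higher in 4 of 4 fish oil libraries than in every DHA oil library, as its selection required, and the control libraries overlapped both arms. The oils did not differ detectably in the genes that fell against control. The fish oil minus DHA oil difference was 0.01 on the log2 scale for ENSG00000109846, with an interval of -0.51 to 0.54. It was -0.92 for ENSG00000101470, with a wider interval of -2.82 to 0.98. Without DHA oil replicate 1 edgeR called 1 gene, lower in fish oil, and with no filter on low counts it called 14, ENSG00000135245 among them.

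Across all 16013 genes, the fold changes of the oils against control correlated at r = 0.560 (genes are not independent replicates). Both comparisons use the same 3 control libraries. Simulations with no effect of diet, in which both oils shared simulated controls, gave a mean r of 0.542 (0.528 to 0.567). The covariance of the fold changes was 0.0530 against a simulated mean of 0.0398 (0.0376 to 0.0428), a difference of 0.0132. With 0 and 1 genes called in these comparisons, no overlap of calls could be counted. The same sign was seen in 60.8% of genes, against 68.2% in the simulations. The rank correlation was 0.340, with no simulated counterpart. The simulated oils shared their controls too, but genes were drawn independently, so the joint rise of the 21 genes in control replicate 1 had no counterpart. The 3 real controls could not be split into parts of at least 2 libraries each. Part or all of the excess covariance may therefore still come from sharing the controls. The 21 genes lower with both oils, with median log2 fold changes of -3.12 (DHA oil) and -4.20 (fish oil), were among the 16013. How much of the excess these 21 genes carry was not measured.

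The leading axis of variation between tumours did not separate the diets. The first principal component held 26.4% of the variance and set fish oil replicate 4 (-52.9) and fish oil replicate 2 (-21.4) apart from the other libraries, which lay between -1.71 and 19.1. The 10 genes with the most counts took 4.83% of the counts in fish oil replicate 4 and between 6.16% and 7.72% in the other libraries.

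**Figure D3:**
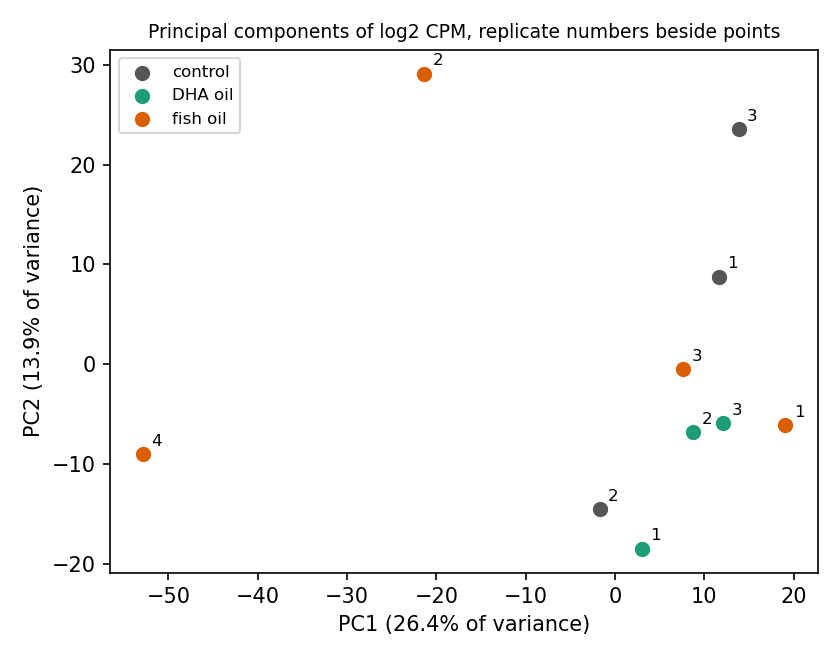
First principal component (horizontal axis, 26.4% of variance) and second (vertical axis, 13.9% of variance) of log2 CPM in the 10 libraries, coloured by diet with the replicate number beside each point. Fish oil replicate 4 lies at -52.9 on the first component, and the 3 control and 3 DHA oil libraries lie between -1.71 and 13.8.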

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

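The tests of sample splits and of single libraries were fixed before their results were seen. The tests of admixture between tissues were chosen only after the results were seen.

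A sample far from the others was looked for in the fish oil group, the only one with 4 libraries, over 12 measures, and 2 stood out, where chance gives about 1 in 20. Both concerned fish oil replicate 3. Its ENSG00000109846 level was 11.5 CPM against 7.02 to 7.21 CPM in the other 3 libraries, a gap of 0.958 of the range. Its mean log2 CPM over the 21 genes lower with both oils was 1.35 against 0.34 to 0.42, a gap of 0.925 of the range, and that mean includes ENSG00000109846. ENSG00000135245 had every DHA oil library below the control mean of 84.3 CPM and every fish oil library above it. Its selection for no overlap between the oils favoured that pattern. The lowest fish oil library, at 84.7 CPM, was barely above that mean, and the controls ranged from 56.8 to 107.7 CPM. Neither oil was called against control for this gene, so opposite directions were not shown. The log2 fold change between the oils was 1.03, and the test of that difference did not pass adjustment in edgeR with the filter on low counts (adjusted p = 0.875, and 0.000835 to 1.00 over the alternatives). It passed in edgeR with no filter and in DESeq2.

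The fall of the 21 genes with both oils was weighed first. Of 100 splits of the 10 libraries into groups of these sizes, 2 called as many genes, the real one with 21 and another with 352. That share is under 0.05 for the count of called genes, with no adjustment over the comparisons and counts tried. By the count at an unadjusted p under 0.05 the real split did not stand out, with 419 genes, as 79 of the 100 gave as many and the highest of the others gave 3797. The split with 352 calls put fish oil replicates 2 and 4 and control replicate 2 together as controls, which points to a structure of the samples apart from diet, as on the first principal component. Without control replicate 1 all 21 genes stayed lower at an unadjusted p under 0.05 (median log2 fold change -2.31), and 3 were still called. The genes had been picked in a fit of all 10 libraries, the other controls among them, so little else could come of this test. It shows a smaller fall against the other controls, but cannot exclude that the remaining calls rested on control replicate 1. A varying share of another tissue in the dissected tumours, or of host reads that align to human genes, may account for the fall of most of these genes. In the 7 oil libraries alone, which the genes were not picked to be high in, their mean pairwise correlation within diets was 0.393 (95th percentile of random sets 0.0853, and 0.274 to 0.452 with each oil library left out), although 2 genes correlated negatively with the rest. Which tissue was not tested, because no identifier was matched to a gene name here. Genes regulated together within tumour cells would correlate as well, so the correlation cannot tell admixture from such regulation. A diet effect on how much of another tissue the tumours held, or on the genes themselves, stays open.

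ENSG00000109846, with a smaller fall and even levels in the 3 controls, was weighed apart. The same admixture may account for part of its fall. Its mean correlation with the other 20 genes in the oil libraries was 0.519, against a 95th percentile of 0.426 in 318 genes of like expression. Without DHA oil replicate 1 the correlation was 0.408. In control replicates 1, 2 and 3 its level changed little, at 25.5, 22.6 and 19.8 CPM. The mean log2 CPM of the 21 genes there was 5.43, 2.94 and 3.53. Its even level beside their uneven ones leaves it unclear that admixture set the whole fall. With the mean of the other 20 genes as a covariate, the log2 fold change of ENSG00000109846 with both oils went from -1.47 (-1.91 to -1.04) to -0.75 (-1.58 to 0.07) and was no longer called. It was -0.84 (-1.64 to -0.03) for DHA oil and -0.67 (-1.59 to 0.25) for fish oil against control. Those 20 genes were picked as lower with both oils, so the covariate follows diet. It tends to shrink any fall with diet and widens the interval, so this fit cannot tell admixture from an effect of diet. A separate effect of diet on this gene stays open.

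For fish oil against control and against DHA oil, chance could not be excluded as the origin of the counts. The 1 gene called for fish oil against control was matched or exceeded in 3 of 35 splits, the real one included, with up to 55 genes in another. The 775 genes at an unadjusted p under 0.05 between the oils were matched or exceeded in 16 of 35 splits, with up to 3190 in the split that grouped fish oil replicates 2 and 4 with DHA oil replicate 1. For DHA oil against control, 10 splits are too few for a share under 0.05. The real one gave 438 genes at an unadjusted p under 0.05, 5 of the 10 gave as many, and the highest of the others gave 508.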

How the results depend on the processing

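The covariate, the joint removal of 2 libraries and the alternatives of the cell cycle sets were chosen only after the data were seen. Other scaling factors (DESeq2 size factors, upper quartile) left all 4 counts of called genes as they were. With no filter on low counts, edgeR called 57 genes for DHA oil against control, 56 for fish oil against control, 14 for fish oil against DHA oil and 76 for both oils against control. The strict filter, which removes genes with a mean under 1 CPM in any group, gave 0 for fish oil against control and 11 for both oils. It removed ENSG00000101470, the 1 gene called for fish oil, whose mean there was 0.794 CPM, so that gene was not tested. DESeq2 called 11 for DHA oil against control, 23 for fish oil against control and 1 between the oils, and 30 for both oils, 15 of them among the 21. limma-voom called 3, 0, 0 and 1 in that order. A fit of only the groups compared called 7 for fish oil against control, and has no counterpart for both oils. With the called genes' score as a covariate, fish oil and both oils against control gave 0 each, as the score was built from these genes. Without control replicate 1 and fish oil replicate 4 together they gave 2 and 3. The cause was not tested for the other moves. Leaving out each library in turn gave 0 to 5 genes for DHA oil against control, 0 to 22 for fish oil against control, 0 to 1 between the oils and 3 to 35 for both oils. Replicate numbers did not pair the samples, since the deviations of 9 same-number pairs correlated at -0.171 to 0.182, 1 of them over 0.1, and 1 of 9 libraries correlated best with its own number. With the replicate block the counts were 1, 0, 0 and 12, and both calls of the G1 set were lost. Of the values of single genes and the G1 set under all alternatives, 180 kept their side of the threshold, 17 passed it, 23 lost it and 0 changed direction. The planned host marker covariate and the alternatives for the fixed gene lists were not run, as no identifier could be matched to a symbol. At these depths the simulated 2-fold changes were recovered in 67% to 73% of genes. That does not bound what was missed in genes that vary more between libraries, or in comparisons where few genes change. In DHA oil against control, ENSG00000101470 was 17.2-fold lower and was not called with the filter.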

Other observations

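The test of fish oil replicate 4 was fixed before its result was seen, while the cell cycle sets themselves were chosen after the identifiers had been seen.

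Cell cycle genes differed little between diets. The sets hold 100 genes each for G1, S and G2/M phase, derived from sorted human embryonic stem cells, so they may track other properties in a tumour line. The mean log2 CPM of the G1 set was 5.14 ± 0.04 in control (SD, n = 3), 5.12 ± 0.02 in DHA oil (SD, n = 3) and 5.21 ± 0.11 in fish oil (SD, n = 4). By camera with a preset correlation it was higher in fish oil than in control (median log2 fold change 0.06, adjusted p = 0.0151) and than in DHA oil (median 0.11, adjusted p = 0.00139), though 0 of its genes passed the test singly. Both calls were lost with an estimated correlation (adjusted p = 0.522 and 0.563) and in fry (adjusted p = 0.541 and 0.488). They were also lost in camera with the replicate number as a block (adjusted p = 0.742 and 0.144). The S set had medians of -0.04 in fish oil against control (adjusted p = 0.0855), -0.03 in fish oil against DHA oil (adjusted p = 0.249) and -0.01 in DHA oil against control (adjusted p = 0.728), and the G2/M set had medians of 0.06, 0.04 and -0.02 in the same order (adjusted p = 0.135, 0.181 and 0.859).

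The higher G1 set may rest on a single tumour. Fish oil replicate 4 had the highest G1 mean of the 10 libraries (5.35), the lowest S mean (5.63), the highest G2/M mean (5.48) and the most distant place on the first principal component. Without it the median fold change of the G1 set between the oils went from 0.11 to 0.04 and the camera adjusted p to 0.144 (0.000104 to 0.563 over the alternatives), and against control the median went to 0.02 (adjusted p = 0.695). Against control the call was also lost without fish oil replicate 2 (adjusted p = 0.0578) or control replicate 3 (adjusted p = 0.108), with medians of 0.05 and 0.06 that stayed near the 0.06 in all libraries. Whether that tumour differed in growth or in handling was not measured.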
